A study of Homo sapiens with 2 samples.

How the data were processed

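Total RNA of 2 cultures of the HCT15 colorectal cancer cell line, 1 that received Cas9 with a guide RNA against ARID3B and 1 control, was measured on 1 Affymetrix array each. Per the labels' protocols, cells were grown in RPMI medium with fetal bovine serum, RNA was extracted with Trizol, and biotin-labelled cRNA was prepared by the manufacturer's standard procedure. The position of the guide, the amount of RNA or spike-in used, and whether the cells were a clone or a pool are not given in the sources used here.

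The deposited values are log2 expression values made with RMA, per the submitters' processing notes, which give no version. RMA subtracts background, sets the arrays to a common distribution by quantile normalisation and summarises the probes of a probe set on the log2 scale. Quantile normalisation removes any difference in total RNA between the arrays, so that a gene's difference is relative to the other genes. Which arrays were normalised together is not given in the sources used here. RMA also compresses differences of dim probe sets.

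The values covered 54675 probe sets, of which 62 were control probe sets. Of the other 54613, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none, and the last 2 kinds gave no gene value. Symbols were updated by Entrez identifier through a RefSeq gene table of assembly GRCh38.p14, in which 41037 probe sets were found and no symbol changed, and 54 kept the annotation's symbol. That table was also used for the chromosome, neighbour order and length of genes, and none of its coordinates is printed. XIST and Y-linked genes were left out. A gene was represented by its probe set with the highest mean of both arrays, and it was compared when the higher of its values was at or above 4.59, the median of all non-control probe sets (the floor). That left 12830 of 19740 genes. All differences are the knockout-labelled minus the control array.

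With 1 array per group no test was possible, and no p-value or standard deviation is given. Precision was described by the scaled median absolute deviation of gene differences in 10 bins of mean expression, 0.255 to 0.436, and by the probe sets of 1 gene. Over 6294 genes with at least 2 probe sets above the floor, the differences of the 2 brightest correlated at r = 0.643 across genes. The gap between these 2 differences had a scaled median absolute deviation of 0.266. Technical and biological variation cannot be separated this way. The share of lower genes has an exact (Clopper-Pearson) 95% interval that covers counting error only.

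Before the data were examined, 44 gene lists were fixed. The median difference of each list with at least 5 members above the floor was ranked among 10000 random lists of the same size, matched in 20 bins of mean expression, and a list stood apart under the percentile 2.5 or over 97.5. Some members were without a single-symbol probe set in the annotation used and were left out. Chromosomes were compared in the same way. Genes named in the text followed a rule fixed in advance. It took ARID3B, then the 15 highest and the 15 lowest genes whose probe sets above the floor all differed in the same direction. A gene with 1 such probe set met this condition without a check, as did most of the 15 highest and several of the 15 lowest. The rule added CD274, LGR5, HES1 and KDM4C, and for each list described up to 4 members with the largest difference. A list member whose probe sets differed in direction is named with that said.

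The alternatives were no floor, a floor at the 75th percentile (the higher floor), the mean of a gene's probe sets, leaving out probe sets marked as matching several transcripts or genes, removing a loess trend of the difference on intensity (span 0.3), centring each array on its median, scaling on ribosomal protein genes, and lists without shared members. For the counts, thresholds of 1.5-fold and 3-fold and 64 linear units added to both arrays were also run. Scaling on the poly-A spike-ins, and raising values under the floor to it, were added after the data were seen. Where a named gene was under the floor on 1 array, its fold is given as a bound, the brighter value against the floor.

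The procedure was tested on simulated data for this comparison with noise of SD 0.25 per array, over 12875 genes. Of 50 genes planted at a difference of 1.5, 88% were called 2-fold higher, and of 50 planted at -1.5, 92% were called lower. All genes planted at 3 and -3 were called. Changes were planted only in genes well above the floor, so these rates do not cover dim genes. Of 12675 unchanged genes 69 were called, and of 400 unchanged lists 17 (4.25%) fell outside the central range. The noise was drawn independently for each probe set, so the rate for lists does not cover genes that vary together. The same SD was used at every expression level, although the real spread of differences ran from 0.255 to 0.436 by bin. The rate of false calls therefore need not hold at each level. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.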

Results

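Gene expression was measured in HCT15, an established human colorectal adenocarcinoma cell line, with 1 array of cells that received Cas9 and a guide RNA against ARID3B and 1 array of control cells. ARID3B encodes a DNA-binding protein of the AT-rich interaction domain family. The labels name the edited cells an ARID3B knockout, and the comparison asks how their transcripts differed from those of the control. Each array gave RMA-normalised log2 values for 54675 probe sets, and the medians of the arrays were 4.59 and 4.59 after the authors' normalisation. After the floor on dim genes, 12830 of 19740 genes (65.0%) were compared. With 1 array per group there was no replicate check and no test, so that every difference below describes these 2 arrays and the number of arrays limits the precision.

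The ARID3B transcript was higher, not lower, on the array labelled knockout. Its value was 6.09 on that array and 5.12 on the control array, a difference of 0.97 on the log2 scale or 1.95-fold. The spread of differences among genes of similar expression was 0.343 (scaled median absolute deviation). This goes against the direction a loss of the transcript would give, and the array is therefore called the knockout-labelled array throughout. A Cas9 edit need not lower the transcript it alters, and the single ARID3B probe set checks nothing if it lies outside the edited part. Every direction given here rests on the labels, which ARID3B did not bear out. Among 12 measured members of the ARID family, no other gene differed as much in its brightest probe set. The list median of 0.10 lay inside the range of random lists. ARID5B was lower at -0.81, KDM5A was higher at 0.41 and ARID2 was lower at -0.40, each with probe sets that differed in direction. As the mean of their probe sets ARID5B differed by -0.36 and KDM5A by -0.13. A dimmer probe set of ARID2 differed by -1.10.

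More genes were lower than higher on the knockout-labelled array. At a 2-fold threshold 135 genes were higher and 486 were lower, so that 78.3% of these genes were lower (exact 95% interval 74.8 to 81.4, counting error only). The arrays correlated at r = 0.966 across genes, which are not independent replicates, and the scaled median absolute deviation of all gene differences was 0.354. Of 296 genes with a 2-fold difference and at least 2 probe sets, 245 (82.8%) differed in the same direction with all of them, against 61.1% of all such genes. The dimmer value lay under the floor for 12 of the higher and 147 of the lower genes, and a difference against such a value is not a measured fold. These directions are relative to the other genes of the array. The 24 probe sets of the poly-A spike-ins, bacterial transcripts normally added to the RNA before labelling, were 2.28-fold lower on the knockout-labelled array (mean difference -1.19). When the arrays were scaled on them, a choice made after the data were seen, all differences moved up by that amount, and 9130 genes were higher and 44 lower.

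**Figure D1:**
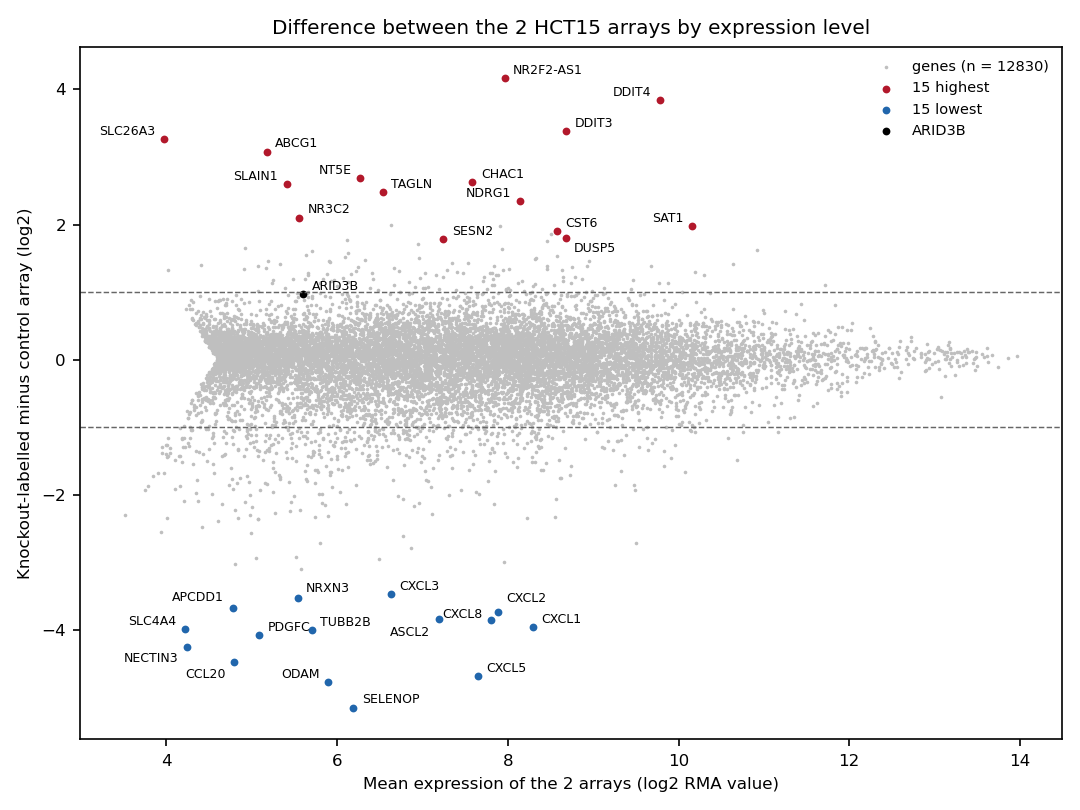
Each grey point is 1 of 12830 genes, placed by its mean log2 value over both arrays (horizontal axis) and its log2 difference, knockout-labelled minus control array (vertical axis). Dashed lines mark a 2-fold difference, and the 15 highest genes (red), the 15 lowest (blue) and ARID3B (black, 0.97) are named. NR2F2-AS1 lies at 4.16 and CXCL5 at -4.68, both measured above the floor on both arrays, while several of the other named genes were under it on 1 array.

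Among the 15 highest genes on the knockout-labelled array, NR2F2-AS1, a long non-coding RNA, was 17.9-fold higher (4.16). DDIT4, an inhibitor of mTORC1 signalling, was 14.4-fold higher (3.85), and DDIT3, the transcription factor CHOP, was 10.5-fold higher (3.39). SLC26A3, the chloride-bicarbonate exchanger of colonic enterocytes, had a control value of 2.34, under the floor of 4.59. Set against the floor in place of such a value, it was at least 2.02-fold higher, the cholesterol exporter ABCG1 at least 4.36-fold, the microtubule-associated SLAIN1 at least 4.35-fold and the mineralocorticoid receptor NR3C2 at least 4.05-fold. The ecto-5'-nucleotidase NT5E differed by 2.69 and the glutathione-degrading enzyme CHAC1 by 2.63. The other probe sets of ABCG1 and NT5E differed by less, 1.45 and 1.24, so that the values of both hold for their brightest probe set alone. TAGLN, an actin-binding protein, differed by 2.48 in its brightest probe set and by 0.26 once probe sets that can match several transcripts were left out. NDRG1 (2.35), the polyamine acetyltransferase SAT1 (1.97), the cystatin CST6 (1.90), the ERK phosphatase DUSP5 (1.80) and SESN2 (1.78) completed the 15.

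The lowest genes held a group of chemokines. CXCL5 was 25.7-fold lower (-4.68), CXCL1 15.6-fold (-3.96) and CXCL8 14.5-fold (-3.86), and CCL20, at 2.56 under the floor on the knockout-labelled array, was at least 5.43-fold lower when set against the floor. All are secreted attractants of leukocytes. CXCL2 (-3.74) and CXCL3 (-3.48) belonged to the same family, and for CXCL2 the difference was -1.28 without probe sets that can match several transcripts. A further 8 of the 15 were under the floor on the knockout-labelled array and have only such a bound, so that no order is read among them. SELENOP, a secreted selenium carrier, was at least 18.1-fold lower, but its other probe set differed by -1.21. The bound was 12.9-fold for ODAM, 3.43-fold for the adhesion molecule NECTIN3, 5.81-fold for the growth factor PDGFC, 8.68-fold for the tubulin TUBB2B and 3.08-fold for the sodium bicarbonate cotransporter SLC4A4. For the Wnt inhibitor APCDD1 it was 4.05-fold and for the synaptic adhesion molecule NRXN3 6.57-fold, where the mean of the NRXN3 probe sets differed by -2.19. ASCL2, a transcription factor of intestinal stem cells, was 14.3-fold lower (-3.84).

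Of 43 gene lists fixed before the data were examined and tested, 8 stood above and 7 below the central 95% of random lists. The random lists were matched on mean expression. Chance would put 2.15 lists outside that range if genes varied independently, which the members of a list need not do. Of the 15 lists outside, 10 stayed outside in the same direction under every alternative run on them. The percentiles describe these arrays and are not p-values.

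**Figure D2:**
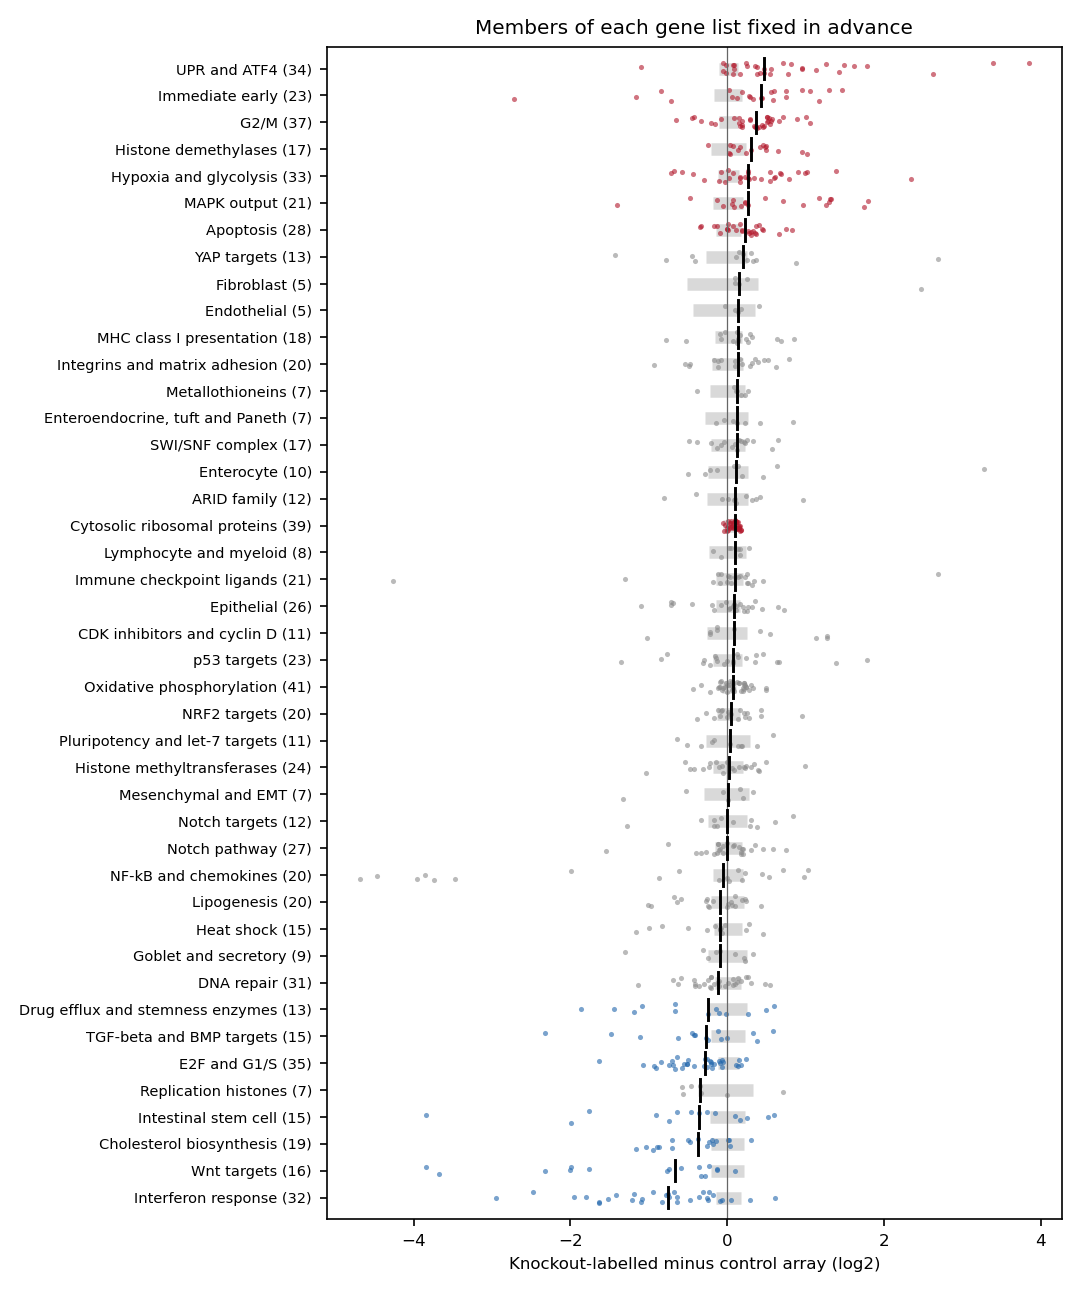
Each dot is a measured member of a gene list, placed by its log2 difference, knockout-labelled minus control array, with the number of members in brackets. Black lines are list medians and grey bars the central 95% of medians of random lists. Red lists stood above that range, blue lists below it and grey lists inside it, from 0.47 for the unfolded protein response and ATF4 list to -0.75 for the interferon list.

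Genes of the unfolded protein response and of ATF4, a transcription factor of the integrated stress response, were higher together on the knockout-labelled array. Their median difference was 0.47, above all 10000 random lists, and 29 of 34 members lay above 0. A 2-fold difference was found in 9 members upward and 1 downward, led by DDIT4, DDIT3, CHAC1 and SESN2. Hypoxia and glycolysis genes had a median of 0.27, also above all random lists, with 25 of 33 members above 0. NDRG1 (2.35), the angiogenic factor VEGFA (1.39), the histone demethylase KDM3A (1.02) and the MYC antagonist MXI1 (0.999) differed most. The apoptosis list had a median of 0.23 (percentile 99.7), with no member past 2-fold. Its largest differences were in the death receptors TNFRSF1A (0.82) and TNFRSF10B (0.66), in PMAIP1 (0.46), and in MCL1 (0.75), an anti-apoptotic gene whose probe sets differed in direction, with a mean of 0.15. That list fell back inside the random range with a median of 0.06 when probe sets were averaged.

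Immediate early and MAPK output genes were also higher as lists on the knockout-labelled array. The immediate early list had a median of 0.43, above all random lists, with 19 of 23 members above 0. Of these 23, 4 were at least 2-fold higher and 2 lower. ZFP36 (1.46), FOSL1 (1.30) and EGR1 (1.18) were higher, while the nuclear receptor NR4A3, under the floor on the knockout-labelled array, was at least 5.96-fold lower. For MAPK output genes the median was 0.27 (percentile 99.7), and 7 of 21 were at least 2-fold higher and 1 lower. Across the alternatives this median ranged from 0.20 to 0.60. The phosphatases DUSP5 (1.80) and DUSP6 (1.33) and the EGF receptor ligand EREG (1.75, and 0.64 in its other probe set) were higher, and the transcription factor ETV1 was lower (-1.41, or -0.84 as the mean of its probe sets).

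Cell cycle genes divided by phase. The G2/M list had a median of 0.37, above all random lists, with 30 of 37 members above 0, among them the phosphatase CDC25C (1.06), the mitotic kinesin KIF2C (1.01), NEK2 (0.89) and DLGAP5 (0.71). The E2F and G1/S list had a median of -0.28, below all random lists, with 30 of 35 members below 0, among them the cyclin CCNE2 (-1.63), the flap endonuclease FEN1 (-1.07), GINS2 (-0.93) and GINS3 (-0.90). GINS2 differed by -0.16 without probe sets that can match several transcripts. The difference between these lists was not tested. The list of CDK inhibitors and cyclins D lay inside the random range at 0.08, although CDKN2D (1.28), CDKN1C (1.28) and CDKN1B (1.14) were each more than 2-fold higher. Across the alternatives its median ranged from 0.012 to 0.41 and its percentile reached 99.7, outside the range. CDK6 was lower at -1.03, with probe sets that differed in direction and a mean of -0.61. The median of p53 targets was 0.08 and that of DNA repair genes -0.11, both inside. Under the alternatives the DNA repair median reached -0.22 and its percentile 0.325, outside the range.

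The interferon response list had the lowest median of all. It stood at -0.75, below all random lists, with 29 of 32 members below 0 and 12 at least 2-fold lower. IFI44 (-2.95), IFIT3 (-1.96) and the antiviral enzyme RSAD2 (-1.80) were among the lowest. SAMD9, under the floor on the knockout-labelled array, was at least 2.10-fold lower, and no rank is read from it. The NF-kB and chemokine list lay inside the random range, with a median of -0.05 and a mean of -1.17. Of its 20 measured members 7 were at least 2-fold lower, the leading ones CXCL5, CCL20, CXCL1 and CXCL8, and 1 was higher. It lay below all random lists, at -1.30, with the higher floor. That floor left out dimmer members, most of them with differences near or above 0, so these medians cover different members. Antigen presentation by MHC class I had a median of 0.14, inside the range. Under the alternatives that median reached 0.31 and its percentile 99.7, outside the range.

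Wnt target genes were lower together on the knockout-labelled array. Their median was -0.66, below all random lists, with 15 of 16 measured members below 0 and 6 at least 2-fold lower. Across the alternatives this median ranged from -0.74 to -0.34. ASCL2 (-3.84), APCDD1, the pseudoreceptor BAMBI (-2.33) and the transcription factor SP5 (-1.9997) differed most. The intestinal stem cell list, which shares several of these genes, had a median of -0.36 (percentile 0.29), with ASCL2, TNFRSF19 (-1.996), the ubiquitin ligase ZNRF3 (-1.76) and ALCAM (-0.90) lowest. As the mean of its probe sets TNFRSF19 differed by -1.13. Without the members that it shares with other lists the stem cell list lay inside the random range at -0.21. Across the alternatives its median ranged from -0.51 to -0.14. LGR5, the stem cell receptor, was under the floor on both arrays in both of its probe sets and was not compared. TGF-beta and BMP targets had a median of -0.27 (percentile 0.71), led by BAMBI, BMP4 (-1.49), SMAD6 (at least 2.02-fold lower) and SMAD7 (-0.62). That list was inside the range at -0.08 with no floor.

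Notch target genes did not stand apart, with a median of 0.00 (percentile 41.7), and the Notch pathway list had a median of 0 (percentile 34.2). HES1, a direct Notch target, was higher by 0.61 and HES4 by 0.84, while HES2 was lower (-1.28) and ID1 was higher (0.39). Pluripotency and let-7 targets had a median of 0.03 and a mean of -0.03. The drug efflux and stemness enzyme list had a median of -0.24 (percentile 2.43), at the edge of the range. The transporters ABCB1 (-1.86) and ABCG2 (-1.44) and the aldehyde dehydrogenases ALDH1A3 (-1.18) and ALDH3A1 (-1.08) were lowest. With the higher floor the list lay inside, at percentile 5.02. Across the alternatives its median ranged from -0.83 to -0.17 and its percentile from 0 to 5.02.

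Histone demethylases were higher as a list, with a median of 0.30 (percentile 99.6) and 16 of 17 members above 0. KDM3A (1.02), KDM1B (0.96), KDM1A (0.65) and KDM6B (0.50, or 0.28 as the mean of its probe sets) led, and KDM4C, a demethylase of histone H3 lysine 9, was 1.38-fold higher (0.46). KDM3A also belongs to the hypoxia list. Histone methyltransferases (0.03) and SWI/SNF subunits (0.12) lay inside the range. Immune checkpoint ligands had a median of 0.10 and a mean of -0.03. CD274, which encodes PD-L1, differed by -0.09, less than the spread of 0.308 among genes of similar expression, with values of 4.53 and 4.62 close to the floor. Its other probe set stood at 3.72 and 4.49, under the floor on both arrays, a difference of -0.77, so that CD274 was too dim to be judged. In that list NECTIN3 and NT5E (2.69) differed most, followed by CD47 (-1.30), whose probe sets differed in direction with a mean of -0.50. CEACAM1 was under the floor on the control array, and its bound of at least 1.06-fold gives it no rank.

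Cholesterol biosynthesis genes were lower, with a median of -0.37 (percentile 0.04) and 15 of 19 members below 0. LSS (-1.16), the squalene epoxidase SQLE (-1.03), SC5D (-0.95) and IDI1 (-0.89) were lowest, but IDI1 differed by -0.14 without probe sets that can match several transcripts. Lipogenesis genes (-0.09) were inside the range. Cytosolic ribosomal protein genes had a median of 0.10 (percentile 98.0), with 34 of 39 above 0 and no member past 2-fold. The largest were RPS9 (0.18), RPS18 (0.18), RPL8 (0.17) and RPS3 (0.16), and the list returned to the random range at 0.07 after the intensity trend was removed.

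The other lists lay inside the random range, although under an alternative enterocyte markers reached percentile 98.25 and replication histones 0.33. Their medians were 0.11 for enterocyte, -0.09 for goblet, 0.13 for enteroendocrine, tuft and Paneth, 0.09 for epithelial and 0.01 for mesenchymal markers, the last with a mean of -0.17. YAP targets stood at 0.21, heat shock genes at -0.09, NRF2 targets at 0.04, oxidative phosphorylation at 0.07, metallothioneins at 0.13, replication histones at -0.34, and integrins and matrix adhesion at 0.13. Markers of cell types other than the epithelium were also inside, at 0.15 for fibroblast, 0.10 for lymphocyte and myeloid and 0.14 for endothelial genes, with 5, 8 and 5 members above the floor. No measured cancer-testis antigen reached the floor.

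The control probe sets were set beside these differences. The hybridisation controls, added after labelling, differed by a mean of -0.14, and all 18 were lower on the knockout-labelled array. The 3-prime minus 5-prime value was -0.03 on the knockout-labelled and -0.02 on the control array for GAPDH, and 0.67 and 0.73 for ACTB.

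**Figure D3:**
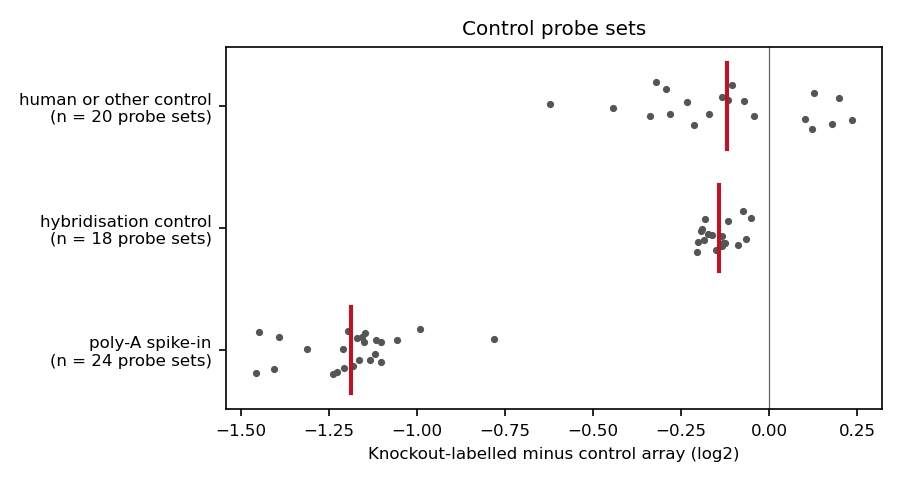
Each point is a control probe set, placed by its log2 difference, knockout-labelled minus control array, and red lines are means. The 24 poly-A spike-in probe sets lie between -1.46 and -0.78, apart from the 18 hybridisation controls, whose mean is -0.14.

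By chromosome, 7 of 23 chromosomes lay outside the range of random gene sets, but by small amounts. Chance would put 1.15 there if genes varied independently. Chromosomes 16, 17 and 19 were higher and 2, 4, 18 and 21 lower, from a median of 0.10 on chromosome 19 to -0.07 on chromosome 21. With no floor chromosomes 16, 17, 18 and 21 lay inside the range (percentiles 94.8, 80.8, 3.80 and 3.87), and 2, 4 and 19 stayed outside under every alternative run. Chromosome 4 held CXCL5, CXCL1, CXCL8, CXCL2, CXCL3, ODAM, PDGFC and SLC4A4 of the lowest genes, but also NR3C2 and EREG, which were higher. Whether these differences share a regional cause was not tested. On chromosome 15, which holds ARID3B, 274 genes proximal to it had a median of 0.07 and 139 genes distal to it also 0.07.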

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

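The tests of swapped labels, of RNA per spike-in, of RNA degradation and of the nutrient state were chosen only after the results were seen. The other tests in this part were set before them.

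Probe sets that gave no gene value also differed between the arrays, and they hold signal that the comparison did not use. Among 3505 probe sets with no gene symbol at or above the floor, 62 were 2-fold or more higher on the knockout-labelled array and 101 lower. Among 1166 with several symbols, 25 were higher and 46 lower. These shares were 1.77% and 2.88% with no symbol and 2.14% and 3.95% with several. For probe sets with 1 symbol they were 1.34% and 4.01%. The highest of those with no symbol stood at 9.61 on the knockout-labelled array and the next at 7.79, with control values of 2.71 and 1.404 under the floor. Set against the floor they were at least 32.5-fold and 9.20-fold higher. At the other end 1 probe set stood at 3.27, under the floor, against 5.86 and was at least 2.41-fold lower, and another stood at 6.25 against 8.61 (-2.36).

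ARID3B was higher on the knockout-labelled array. An intensity trend or scaling between the arrays is argued against, since the difference stayed at 0.896 or more under loess, median centring and ribosomal scaling, more than 2 times the spread of 0.343 among similar genes. Swapped labels cannot be told apart from a true higher transcript, because 1 probe set at 0.967 decides nothing. An edit that leaves or raises the transcript stays open as well, untested, since the guide's position is not given in the sources used here.

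More genes were lower than higher. Dim genes near background are argued against, as 72.7% of genes past 2-fold were lower with the higher floor. So is scaling or an intensity trend left after normalisation on the arrays' own genes, with at least 73.1% lower under each of the 3 corrections. A difference in RNA per spike-in stays open. The poly-A spike-ins differed by -1.19 and the hybridisation controls by only -0.14, which may reflect more RNA per spike-in on the knockout-labelled array or less spike-in added, and these cannot be told apart because no source used here states the amounts. The edit itself was not tested against these.

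The stress lists were higher while the interferon and Wnt lists were lower, and several chemokine genes were lower although their list lay inside the random range. RNA degradation is argued against by the 3-prime minus 5-prime values of GAPDH and ACTB, which differed between the arrays by at most 0.064. An intensity trend left after normalisation is argued against by the interferon median of -0.78 after loess, with the ATF4 and Wnt lists also still outside. The nutrient state or density of the culture stays open. The hypoxia and ATF4 lists were higher, and a ribosome biogenesis list lay at percentile 0, as a depleted culture could give, but with 1 culture per group this cannot be told apart from the edit. Clonal differences between the cultures and the loss of ARID3B itself also stay open, untested.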

How the results depend on the processing

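The scaling on poly-A spike-ins and the raising of values to the floor were chosen after seeing the data. The other alternatives were fixed before the data were examined. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out and no other split of the samples made. The counts of 135 higher and 486 lower genes moved to 749 and 1348 at 1.5-fold, to 25 and 133 at 3-fold, and to 46 and 117 with 64 linear units added. The lower count was 290 with the higher floor, where fewer genes were compared. The lower share was between 71.8% and 84.2% in all of these planned settings except 1.5-fold, where it was 64.3%. Scaling on poly-A spike-ins gave 9130 higher and 44 lower genes, or 0.480% lower, because it moved every difference up by 1.19. With values under the floor raised to it, 131 genes were higher and 406 lower. These last settings and the linear units were run for the counts only.

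No list that stood apart changed sign under the alternatives run on lists. Scaling on the poly-A spike-ins was not among these. Its upward shift is larger than the size of any lower list median and would turn those medians positive. The 5 that returned to the random range did so as follows, and the cause was not tested. Apoptosis gave 0.064 with averaged probe sets, 0.20 without shared members and 0.0087 without probe sets matching several transcripts. Ribosomal proteins gave 0.069 after loess, 0.11 with averaged probe sets, 0.10 with no floor and 0.12 without multiple-match probe sets. Drug efflux gave -0.24 with the higher floor and -0.25 after loess, stem cell genes -0.21 without shared members, and TGF-beta targets -0.27 with the higher floor and -0.085 with no floor. In 9 cases a list inside the range moved outside, among them NF-kB and chemokines at -0.36 without multiple-match probe sets. The other lists concerned were CDK inhibitors and cyclins D, DNA repair, MHC class I presentation, enterocyte markers and replication histones. The number of chromosomes outside was 11 with averaged probe sets, 9 after loess and 6 with no floor, against 7, of which 3 stayed outside throughout. Chromosome 17 was inside after loess (97.45) and 18 with averaged probe sets (2.75). ARID3B stayed between 0.90 and 1.01. Dim genes are the least certain, since RMA compresses differences near background.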

Other observations

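The tests of the ribosome biogenesis list, of the ZNF genes and of a length trend as the whole cause were chosen only after the results were seen. The other tests in this part were set before their results, but the interval of the gene length test and the chaperone list without shared genes were added after the first values were seen.

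Genes of ribosome biogenesis, which make and assemble ribosomes in the nucleolus, were lower on the knockout-labelled array, with a median of -0.38 that lay below all 10000 random lists and 29 of 31 members below 0. RRS1 (-1.48), POLR1A (-0.91) and PNO1 (-0.87) were lowest. NOP16 (-0.83) followed, with probe sets that differed in direction. This list was not among the 44 fixed at the start.

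Zinc finger genes were lower as a family. A shift of the ZNF genes as a whole is a hypothesis that came from the lowest genes and was tested on the same data. The median of 294 genes with a ZNF symbol was -0.14, below all random lists, and 189 lay below 0. Of them 10.2% were at least 2-fold lower, against 3.64% of other genes, and 2 were higher.

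A folding stress of the endoplasmic reticulum may go with the higher ATF4 targets. Luminal chaperones of the endoplasmic reticulum had a median of 0.24 (percentile 99.92), led by SEC24D (0.82), a coat protein of export vesicles that the list also held and no chaperone, and by HSPA5 (0.47), HYOU1 (0.47) and P4HB (0.41). None of the 19 genes was past 2-fold, only SEC24D was past 1.5-fold, and 5 lay below 0. Of the 19, 10 also belong to the unfolded protein response and ATF4 list. The other 9 alone, SEC24D among them, had a median of 0.25 (percentile 98.9). An amino acid response through ATF4 was not decided, since cytosolic aminoacyl-tRNA synthetases stood at percentile 91.2, short of the bound set in advance, with CARS1 (0.99), AARS1 (0.82) and SARS1 (0.75) highest. The mitochondrial synthetases, a comparison list, stood at percentile 63.8.

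A gain or loss of the whole part of chromosome 15 beyond ARID3B, carried by all cells, is argued against. The distal genes differed from the proximal ones by 0.0011 in median, and a single-copy change was set in advance at 0.4 or more. A shorter part or a change in only some of the cells could go unseen in this value, as could a change of the whole chromosome. Over the 414 compared genes of chromosome 15 the median was 0.073 (percentile 96.67), also under 0.4. This argues against a gain or loss of the whole chromosome carried by all cells. After loess the percentile was 97.84, just above the random range, at a median of 0.053.

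For the small shifts between chromosomes, the value set in advance met its bound. Between the longest and the shortest 20% of genes the median differed by -0.042, under the 0.05 below which a gene length trend was to be excluded. A bootstrap 95% interval added after the value was seen, -0.067 to -0.014, crosses that bound, so the margin is within the spread and a trend is left open on that measure. As the whole cause it is argued against by a count that was chosen as a test after both values were seen. With the length trend removed 8 chromosomes lay outside the random range, against 7 without.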
